A study of Homo sapiens with 2 samples.

How the data were processed

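MicroRNA levels were profiled by stem-loop real-time PCR in THP-1 cells, a human monocytic leukaemia line, given 10 nM estradiol or the ethanol vehicle. Per the labels' protocols, RNA was extracted with TRI-Reagent, the RNA of 3 cultures per treatment was pooled, and 30 ng was reverse transcribed with Megaplex primers in 2 pools covering 754 miRNAs and 4 endogenous controls. Per the same protocols, the product was pre-amplified and run on TaqMan MicroRNA Arrays v3.0, cards A and B, on a 7900HT instrument. The treatment time, the Ct software, its baseline and its threshold settings are not given in the sources used here.

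The deposited tables held 768 wells each, 384 per card. Per the file headers, the first table gives raw threshold cycles (Ct), in which a lower value is a more abundant RNA and an assay with no Ct is listed as undetermined. Per the file headers, the authors deposited a second table as a ratio to a housekeeping RNA, 2 to the power of minus delta Ct. In the values, each ratio was relative to the mean Ct of the 4 U6 wells of the same card and sample. The authors' deposited fold table gives the estradiol over vehicle fold of 168 assays, controls included. It differed from the quotient of the deposited ratios by more than 1e-09 on the log2 scale in 0 assays, so it is no independent check of them. The card of an assay was taken from the number of digits in its assay number, which divides the wells into equal sets that each hold a full set of controls. The U6 wells have different names on each card and were treated as the same control. Names were harmonised for letter case and for a misspelt species prefix, and # marks the minor (star) arm of a miRNA. 2 assays share the name miR-378 and carry their assay numbers in the text.

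The following choices were made before the data were examined. The main measure was log2 of the deposited ratio with estradiol over that with vehicle. A miRNA was detected at Ct under 35 and compared when detected in both samples, and it was counted as higher or lower at a difference of at least 2-fold. With 1 pooled sample per treatment, no p-value, SD or test between treatments was computed. For each fixed list with at least 3 compared members, the median log2 ratio was placed among 10000 random lists of the same size, drawn within card and quintile of mean Ct. That percentile describes these samples and is not a test of the treatment. The fixed lists were miR-19, the miR-17 cluster with its paralog clusters, the let-7, miR-15/16, miR-30, miR-29 and miR-181 families, the miR-23-27-24 clusters, myeloid, inflammatory and estrogen-associated miRNAs, markers of epithelial, muscle, neural, liver and other blood or endothelial cells, the chromosome 19 and chromosome 14 clusters, star strands, and the endogenous controls.

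The miRNAs named in the text were set by a rule: miR-19a and miR-19b; the 10 largest differences in each direction among compared miRNAs past 2-fold; up to 5 miRNAs of lowest Ct among those detected in 1 sample alone, for each sample; up to 4 compared members of lowest mean Ct per list; the 5 miRNAs of lowest mean Ct; and all controls. Any other miRNA named was chosen after its values were seen.

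Also set before were these other settings: scaling to the median or mean of the compared miRNAs of each card, to U6 recomputed from raw Ct, to RNU44, to RNU48 or to nothing, the authors' fold, Ct limits of 32, 30, 38 or none, a detection margin of Ct 33, thresholds of 1.5-fold and 3-fold, human main arms alone, each card alone, and random lists matched on size alone. Chosen after the data were seen were scaling to the mean of RNU44 and RNU48, leaving out assays with a Ct under 15, leaving out assays with a Ct within 0.05 of a whole cycle, and the count of miRNAs past 2-fold under 5 scalings at once (U6, card median, RNU44, RNU48 and none).

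The spread of the 4 U6 wells within card and sample, pooled, was 0.066 cycles, which gives 0.094 cycles for a difference between wells. This covers well-to-well error alone, not differences between cultures, reverse transcription reactions or cards. Shares of wells have exact (Clopper-Pearson) 95% confidence intervals, which cover counting error alone. Neighbouring miRNA genes, at most 10000 bp apart, were taken from a RefSeq gene table of assembly GRCh38.p14. The files name no genome build and no coordinate was used otherwise. Of 127 compared miRNAs without a Ct under 15, 114 matched a gene in that table.

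The computations were tested on simulated Ct built from the vehicle values of the 142 compared miRNAs, with a different offset per card and noise of SD 0.30 cycles. With U6 scaling, 20 of 20 miRNAs changed by 2 cycles, 20 of 20 changed by 4 cycles and 0 of 102 unchanged miRNAs passed 2-fold, and scaling to the card median gave the same counts. The simulated U6 wells had the same card offset as the miRNAs, so U6 was a sound reference by construction. In the data U6 did not move with the other controls on card A, so these rates check the computation, not the ratios to U6. For the list percentile, 50 of 50 lists of 5 miRNAs shifted by 1 cycle and 3 of 50 unshifted lists fell outside percentiles 2.5 to 97.5. In the data the compared miRNAs spread more widely, with quartiles of the log2 ratio to U6 of -0.38 and 1.88. The simulated rate for a shift of 1 cycle therefore does not carry over to the lists here. For the permutation of neighbouring pairs, changes were drawn from a normal distribution and not from Ct, and shared ones differed only by the noise. There 50 of 50 sets of 30 pairs sharing a change and 3 of 50 unrelated sets lay under 5% of permutations. In those sets no miRNA was in more than 1 pair, while the data held 44 pairs of 38 miRNAs. The simulated spread was not set from the data either, so these rates do not carry over to the pairs here. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.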

Results

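THP-1 monocytic cells were profiled for 754 miRNAs after 10 nM estradiol or ethanol vehicle. Each treatment was 1 pool of RNA from 3 cultures, so there were no replicates, and the values below describe these pools. At Ct under 35, 183 miRNAs (24.3%) were detected with vehicle and 184 (24.4%) with estradiol, and 142 were detected in both, 75 on card A and 67 on card B. The median Ct of the detected miRNAs was 26.9 with vehicle and 27.9 with estradiol.

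The comparison asked how miRNA levels in monocytic cells differ after estradiol. miR-21, an oncogenic miRNA also induced in inflammation, had Ct 31.0 with vehicle and 27.0 with estradiol and was 62.3-fold higher with estradiol relative to U6, a log2 ratio of 5.96 that was 4.99 over the card median and 3.11 with RNU48. On card A, miR-451, an erythroid miRNA, was also higher, with a log2 ratio of 4.66 to U6, 3.70 over the card median and 1.82 with RNU48. miR-29b had 4.33, 3.36 and 1.48 on these scales, and miR-299-5p had 4.18, 3.21 and 1.33. On card B, where the scalings lay closer together, miR-1243 had a log2 ratio of 6.88 to U6 and 6.30 with RNU48, miR-151-3p 5.86 and 5.28, and miR-625# 4.56 and 3.98. Among the lower miRNAs of card A, miR-29c had a log2 ratio of -3.33 to U6, -4.30 over the card median and -6.17 with RNU48. On the same scales miR-523 had -3.23, -4.20 and -6.08, the epithelial miRNAs miR-203 -2.89, -3.86 and -5.73 and miR-205 -2.02, -2.99 and -4.87, miR-454 -2.13, -3.10 and -4.98, and miR-377 -1.99, -2.96 and -4.84. miR-646, on card B, had -2.82 to U6 and -3.40 with RNU48. Both Ct of miR-21, and 1 Ct each of miR-1243, miR-203 and miR-454, lay within 0.05 of a whole cycle, near which Ct values gathered in these runs, so these 4 are not among the compared miRNAs when such Ct are left out. All miRNAs of this paragraph kept their direction and differed by at least 2-fold under each of 5 scalings, U6, card median, RNU44, RNU48 and none. Each scaling moves all ratios of a card by the same amount, and these miRNAs were picked for their large differences. Keeping past 2-fold thus follows from their size and is no separate evidence that the differences are real.

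Of the 10 largest differences in each direction, 4 came from assays with a Ct under 15 in at least 1 sample. miR-148b# had Ct 34.1 with vehicle and 6.84 with estradiol, a log2 ratio to U6 of 27.01. miR-519b-3p went the other way, with Ct 14.9 and 33.8 and a log2 ratio of -19.15, as did miR-135a, with Ct 11.6 and 28.0 and a log2 ratio of -14.53 (-15.50 over the card median). miR-521 had Ct 9.56 and 7.33 and a log2 ratio of 4.12 (3.15 over the card median). The assays both named miR-378 differed in direction, with a log2 ratio of 6.39 for assay 002243 and -2.92 for assay 000567.

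In total, 56 of the 142 compared miRNAs were at least 2-fold higher with estradiol, 20 were at least 2-fold lower and 66 lay within 2-fold. This split depended on the scaling: it was 40 higher and 39 lower on the card median, 40 and 40 on the card mean, 34 and 47 with RNU44, 20 and 64 with RNU48, 27 and 53 with the mean of RNU44 and RNU48, and 35 and 45 with none. It also moved with the assays that entered, to 34 higher and 11 lower at a Ct limit of 30, and to 22 and 12 without assays with a Ct within 0.05 of a whole cycle. Under all 5 scalings, 20 miRNAs were past 2-fold higher and 19 past 2-fold lower, or 18 and 17 without assays with a Ct under 15. U6 gave the highest card A ratios of the 5, so no card A miRNA called lower to U6 could lose that call. The sign of the ratio was kept under all 5 in 87 of the 142 miRNAs.

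**Figure D1:**
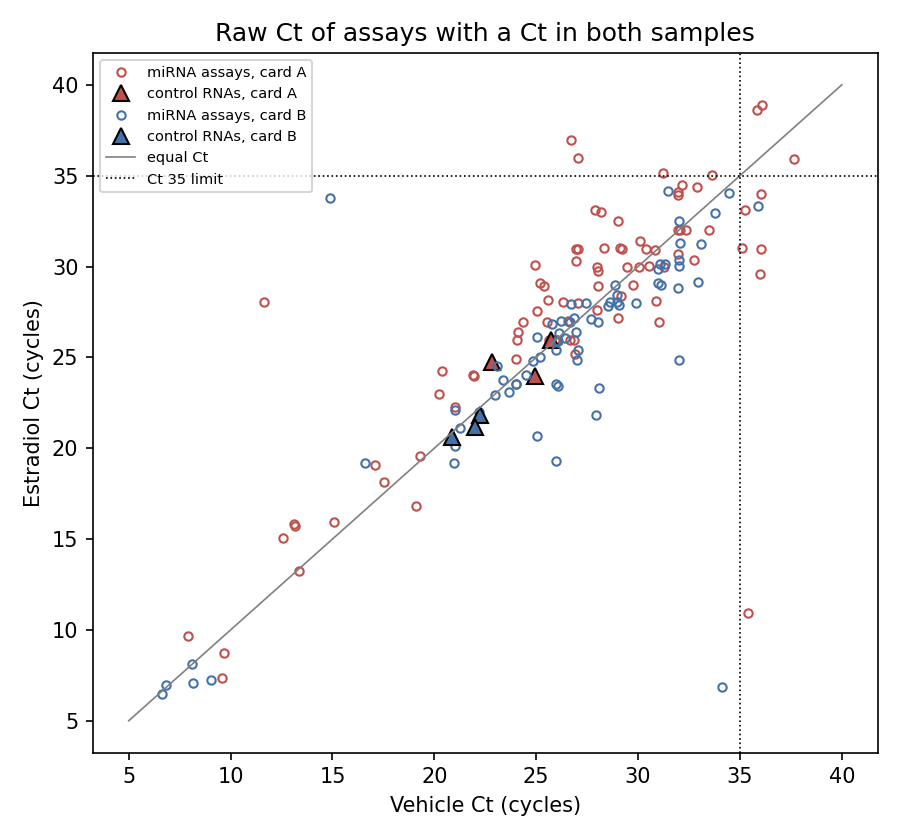
Raw Ct in cycles with vehicle (horizontal) and estradiol (vertical) for every miRNA assay with a Ct in both samples (open circles) and for the control RNAs (triangles), coloured by card; the grey line marks equal Ct and dotted lines the Ct 35 limit. A few assays with a Ct under 15 in 1 sample and a late Ct in the other, among them miR-148b# at 34.1 and 6.84, lie far from the line.

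The control RNAs did not move together. On card A, U6, the small nuclear RNA to which the deposited ratios refer, had a mean Ct of 22.9 ± 0.086 with vehicle and 24.7 ± 0.070 with estradiol (SD over 4 wells of 1 pool), 1.89 cycles later. On card B it had 20.9 ± 0.052 and 20.6 ± 0.050 (SD over 4 wells of 1 pool), a difference of -0.25 cycles. In raw Ct, the small nucleolar RNA RNU44 differed by 0.24 cycles on card A and -0.45 on card B, and RNU48 by -0.96 and -0.83. The plant control ath-miR159a was undetermined in every well. Relative to U6 the median log2 ratio of the compared miRNAs was 0.97 on card A and 0.32 on card B, while in raw Ct it was -0.92 and 0.57. For card A miRNAs the ratio to U6 is thus 0.97 above that over the card median. 7 card A miRNAs, among them miR-155, miR-17 and miR-30b, had raw Ct within 0.1 cycle between the samples and U6-relative folds of 3.55 to 3.91. In all 7, both Ct also lay within 0.1 of the same whole cycle, near which Ct values gathered in these runs.

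**Figure D2:**
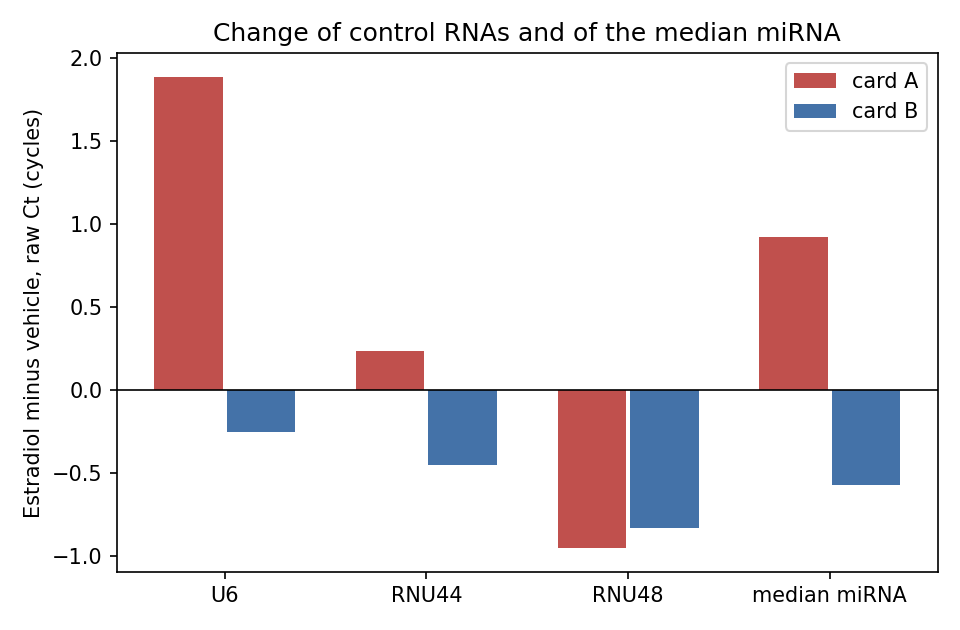
Difference in raw Ct, estradiol minus vehicle, in cycles, for U6 (mean of 4 wells), RNU44, RNU48 (1 well each) and the median of the compared miRNAs, per card; above 0 is a later Ct with estradiol. U6 was 1.89 cycles later on card A and differed by -0.25 on card B.

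miR-19a and miR-19b, members of the proliferation-associated miR-17 cluster, were higher with estradiol relative to U6, a direction that miR-19b lost with RNU48. miR-19a had Ct 33.5 with vehicle and 32.01 with estradiol, a 10.4-fold difference, with a log2 ratio of 3.38 to U6, 2.41 over the card median and 0.53 with RNU48. miR-19b had Ct 26.7 and 26.0, a 5.96-fold difference, with a log2 ratio of 2.57 to U6 and 1.61 over the card median, but -0.27 with RNU48. Both estradiol Ct lay within 0.05 of a whole cycle. The pair was picked because the study is recalled to have followed up miR-19 in these cells, which the labels do not mention. It is therefore not treated as independent evidence of its direction.

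Of the 9 compared members of the miR-17 cluster and its paralog clusters, 6 were at least 2-fold higher and 0 lower relative to U6, with a median log2 ratio of 1.93, 0.96 over the card median but -0.92 with RNU48 and -0.32 with the mean of RNU44 and RNU48. miR-92a had a log2 ratio of 2.79 to U6 and 1.82 over the card median, miR-17 of 1.95 and 0.98, and miR-106a of 1.93 and 0.96, and all 3 were below 0 with RNU48, miR-17 and miR-106a also with the mean of RNU44 and RNU48. The list median is that of miR-106a, whose raw Ct was 25.99 with vehicle and 25.95 with estradiol. Its ratio to U6 thus came almost wholly from the later U6 on card A. The list median lay at percentile 88.2 of the matched random lists. A further 1 member, miR-363, named after its values were seen, was detected with estradiol alone (Ct 24.97).

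Among 3 compared myeloid miRNAs, 2 were higher relative to U6 and 0 lower, with a median log2 ratio of 1.96, 0.99 over the card median but -0.89 with RNU48 and -0.29 with the mean of RNU44 and RNU48, at percentile 84.4. The list held 8 assays, and the others, miR-142-5p, miR-424, miR-503, miR-511 and miR-22, had no Ct in either sample. The myeloid median is that of miR-142-3p, whose raw Ct was 30.06 with vehicle and 29.99 with estradiol. Its ratio to U6 thus came almost wholly from the later U6 on card A. miR-342-3p had a log2 ratio of 3.70 to U6, 2.74 over the card median and 0.86 with RNU48 and stayed above 0 under the 5 scalings, while miR-142-3p had 1.96 to U6 and 0.99 over the card median but -0.89 with RNU48 and -0.29 with the mean of RNU44 and RNU48. miR-223, a marker of the myeloid lineage, had 0.98 to U6 and 0.01 over the card median, but was below 0 with RNU44, with RNU48 (-1.86), with their mean and with no scaling. Among 5 inflammatory miRNAs, 4 were higher and 0 lower relative to U6, with a median of 1.87, 0.90 over the card median but -0.98 with RNU48, -0.38 with the mean of RNU44 and RNU48 and -0.025 with no scaling, at percentile 75.7. The inflammatory median is that of miR-146b-5p, named after its values were seen, with raw Ct 31.96 with vehicle and 31.98 with estradiol. Its ratio to U6 likewise came from the later U6 on card A. Beside miR-21, miR-9 had 3.13 to U6, 2.16 over the card median and 0.28 with RNU48, above 0 under the 5 scalings. miR-155, a mediator of inflammatory signalling, had 1.83 to U6 and 0.86 over the card median but -0.062 with no scaling, -1.02 with RNU48 and -0.42 with the mean of RNU44 and RNU48. A further 2 inflammatory miRNAs, miR-146a (Ct 31.98) and miR-132 (Ct 32.99), named after their values were seen, were detected with vehicle alone and had no Ct with estradiol, and 0 were detected with estradiol alone. miR-99b had 0.14 to U6 but -0.82 over the card median and was below 0 under all scalings run except U6.

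Of 10 compared estrogen-associated miRNAs, 4 were higher and 2 lower relative to U6, with a median log2 ratio of 0.23 to U6 but -0.42 over the card median and below 0 under all scalings run except U6, at percentile 35.7. Beside miR-21 and miR-135a, the members of lowest Ct were miR-34a, at -0.16 to U6 and -1.13 over the card median, miR-206, at 0.32 to U6 but below 0 with the card mean, RNU48 (-0.26) and the mean of RNU44 and RNU48, and miR-302c, at 1.01 to U6 and 0.04 over the card median but below 0 with RNU44 (-0.64), RNU48 (-1.84), their mean and no scaling. Not in these counts, and named after their values were seen, 3 members were detected with vehicle alone, miR-221 (Ct 27.1 with vehicle and 35.96 with estradiol) and miR-26a and miR-26b (both 31.98, with no Ct with estradiol), and 1 with estradiol alone, miR-193b (31.97). In the let-7 family, differentiation-associated miRNAs, 1 of 5 was higher and 1 lower, with a median of 0.18 to U6 but -0.79 over the card median and below 0 under all scalings run except U6, at percentile 36.9. let-7b had a log2 ratio of 2.30 to U6 and 1.34 over the card median but -0.54 with RNU48. let-7e had -1.62 to U6 and -2.58 over the card median, and let-7d -0.83 and -1.80. let-7a, at the median, had 0.18 to U6 and was below 0 under all scalings run except U6.

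In the miR-29 family, miR-29b and miR-29c above were counted as neighbouring genes, and their changes lay 7.65 cycles apart, the widest gap among the neighbouring pairs. An assay of a mature miRNA does not tell which gene it came from, so this gap is not that of a known shared transcript. The vehicle Ct of miR-29b was late, at 32.8. Beside these, miR-29a had a log2 ratio of -0.69 to U6 and -1.66 over the card median. It is the list median, which to U6 is 0.50 without miR-29a, whose Ct was 13.1 with vehicle. That median lay at percentile 10.3. Of the 4 compared miR-30 miRNAs 2 were higher and 0 lower relative to U6, with a median of 1.08 to U6 and 0.20 over the card median but -0.29 with RNU44, -1.08 with RNU48, -0.68 with their mean and -0.18 with no scaling, at percentile 68.9. miR-30b had 1.86 to U6 and 0.89 over the card median but -0.99 with RNU48, -0.39 with the mean of RNU44 and RNU48 and -0.034 with no scaling. miR-30d had 1.70 to U6 and 1.38 over the card median, miR-30c 0.47 to U6 but -0.49 over the card median and below 0 under all scalings run except U6, and miR-30a-5p -0.58 and -0.90. Both compared miR-15/16 members were higher relative to U6, miR-16 at 2.41 and miR-15b at 1.97, over the card median at 1.44 and 0.999, and below 0 with RNU48, at -0.44 and -0.88, and miR-15b was also below 0 with the mean of RNU44 and RNU48, at -0.28. A further 1 member, miR-195, was detected with vehicle alone (Ct 33.6, and 35.03 with estradiol). miR-24, the compared member of the miR-23-27-24 clusters, had 1.27 to U6 and 0.30 over the card median but was below 0 with RNU44 (-0.38), RNU48, their mean and no scaling. The miR-181 family assays, miR-181a and miR-181c, had no Ct in either sample.

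The main arms of 3 epithelial markers were lower with estradiol under every scaling run, with 2 of 3 past 2-fold relative to U6 and a median log2 ratio of -2.02 to U6 and -2.99 over the card median. All 3 are on card A, where U6 gave the highest ratios of the scalings run, so values below 0 to U6 had to stay below 0. The list was set as markers of cells that the culture should not hold. miR-200a had -0.89 to U6 and -1.86 over the card median, beside miR-203 and miR-205 above. Its Ct was 20.2 with vehicle and 23.0 with estradiol, earlier than the 24.0 and 24.9 of the myeloid marker miR-223. By contrast miR-141 and miR-429 had no Ct in either sample, and miR-200b had Ct 36.03 with vehicle and none with estradiol. Whether these assays measured the named miRNAs was not tested. Star arms of this group, chosen after their values were seen, went the other way under every scaling run: miR-200a# had 1.89 to U6 and 1.57 over the card median, and miR-141# 0.96 and 0.64. A further 1 epithelial marker, miR-200c, was detected with vehicle alone (Ct 30.98). The median lay at percentile 3.75 of lists matched on card and Ct and at 0.85 of lists matched on size alone. Of the muscle markers, miR-208 had 0.64 to U6 but -0.32 over the card median and below 0 under all scalings run except U6, and miR-206 is given above. miR-9 was the compared neural marker, with miR-124 detected with estradiol alone, and miR-451 the compared marker of other blood and endothelial cells, with miR-150 detected with vehicle alone. The liver marker miR-122 was detected in neither sample, although its star arm miR-122# had Ct 6.10 with vehicle.

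Of 9 compared chromosome 19 cluster assays, a placental cluster, 2 were higher and 2 lower relative to U6, with a median log2 ratio of -0.08 to U6 and -0.68 over the card median, at percentile 21.8. miR-518b had 0.15 to U6 but -0.82 over the card median and below 0 under all scalings run except U6, and miR-518f -0.59 to U6 and -1.56 over the card median. In this cluster 2 further assays were detected with estradiol alone, miR-522 and miR-520d-5p (Ct 31.0, and 35.11 with vehicle), and 3 with vehicle alone, miR-512-3p, miR-517c and miR-519a. Of these, miR-522, miR-517c and miR-519a had a Ct under 15. So had 4 of the 9 compared assays, miR-518b, miR-518f, miR-521 (among the higher) and miR-519b-3p (among the lower). Without these 4 the median to U6 stayed at -0.08. Of 8 compared members of the imprinted chromosome 14 cluster, 3 were higher and 2 lower, with a median of 0.36 to U6 but -0.28 over the card median and below 0 under all scalings run except U6, at percentile 21.4. miR-376a had 3.62 to U6 and 2.65 over the card median, and miR-410 -0.70 and -1.67, while 3 further members were detected with estradiol alone, miR-539, miR-433 and miR-323-3p, and 2 with vehicle alone, miR-381 and miR-495. All 3 detected with estradiol alone had a Ct under 15, at 6.05, 10.90 and 10.92, and miR-323-3p had Ct 35.4 with vehicle. Of 10 compared star strands, 5 were higher and 1 lower, with a median of 1.18 to U6, 0.86 over the card median and 0.60 with RNU48, at percentile 95.2, and 7 further star strands were detected with estradiol alone and 7 with vehicle alone. Of the latter groups, let-7b#, miR-100#, miR-122# and miR-125b-2# had a Ct under 15, as had the compared miR-148b#. miR-135b# had 2.43 to U6 and 2.11 over the card median, miR-335# -1.34 and -1.66, and miR-551b# -0.20 to U6 but 0.055 with no scaling.

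**Figure D3:**
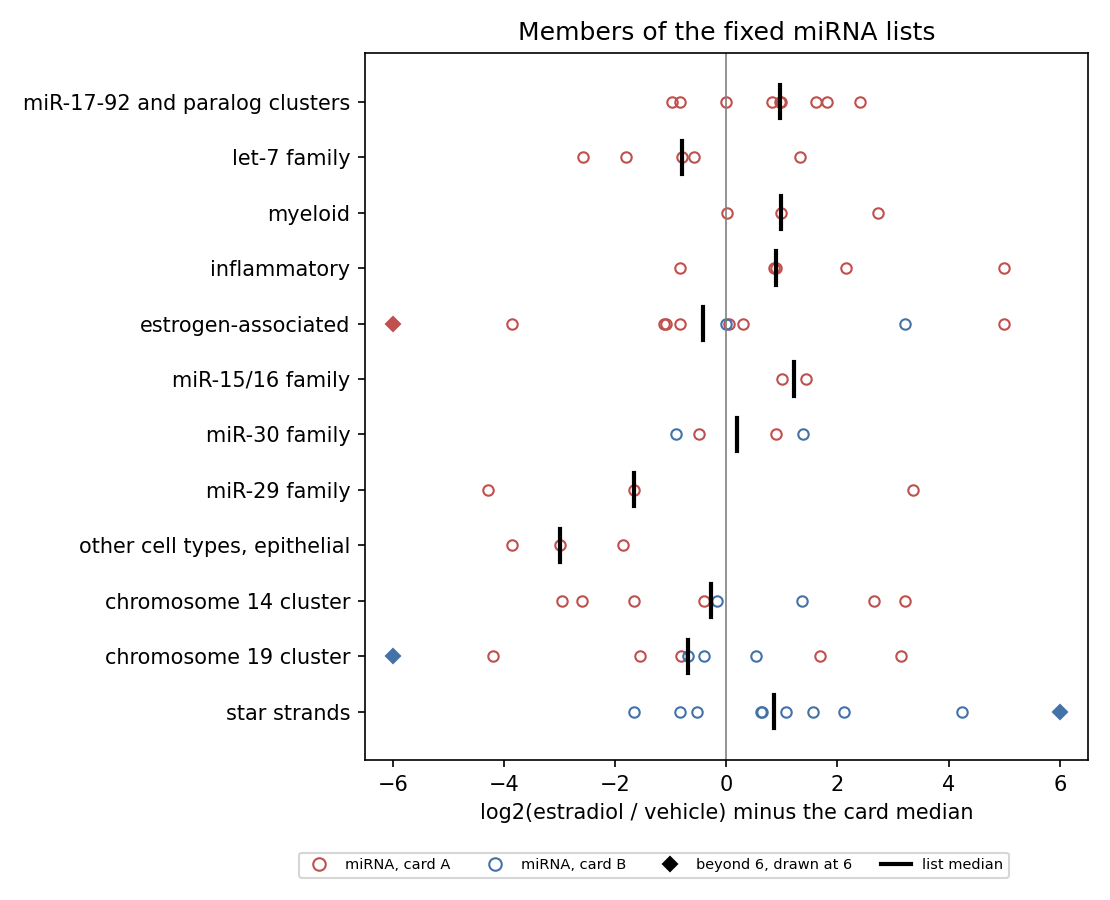
Log2 ratio of estradiol over vehicle minus the card median for members of the fixed lists with Ct under 35 in both samples; circles are miRNAs coloured by card, diamonds lie beyond 6 and are drawn there, and bars are list medians. The epithelial median of -2.99 is below 0 under every scaling run, as had to follow from its U6 value, since U6 gave the highest card A ratios. The miR-17 cluster median of 0.96 turns to -0.92 with RNU48 and the myeloid median of 0.99 to -0.89.

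Detection also differed between the pools. 42 miRNAs were detected with estradiol alone, 35 of them with no Ct with vehicle, and 41 with vehicle alone, 37 of them with no Ct with estradiol. The lowest Ct among those with estradiol alone belonged to miR-539 (6.05), miR-522 (7.04), miR-1233 (7.84), miR-885-3p (8.23) and miR-433 (10.9). Among those with vehicle alone it belonged to miR-122# (6.10), miR-674 (6.28), miR-125b-2# (6.39), miR-874 (7.04) and miR-1259 (7.96). No fold is given for them, as the other sample had no Ct. The 5 compared miRNAs of lowest mean Ct were miR-559, miR-1262, miR-659, miR-1274b and miR-549, with log2 ratios of -0.10, -0.36, 0.86, -0.27 and 1.58 to U6. Of these, miR-559 turned to 0.15 with no scaling.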

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

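Chosen after the data were seen were scaling to the mean of RNU44 and RNU48 and leaving out Ct under 15 or near a whole cycle; all others were chosen before. Against 56 higher and 20 lower miRNAs and the list medians to U6 given above, values that moved by over 1.5 times (counts) or by over the 0.094 cycle well spread (log2 list medians), and named ratios past 2-fold that turned sign, were as follows. With the card median, there were 39 lower miRNAs. List medians with the card median were 0.96 for the miR-17 cluster, -0.79 for let-7, 0.99 for myeloid, 0.90 for inflammatory, -0.42 for estrogen-associated, 0.20 for miR-30, -1.66 for miR-29, -2.99 for epithelial, -0.68 for chromosome 19 cluster, -0.28 for chromosome 14 cluster and 0.86 for star strands. With the card mean, there were 40 lower miRNAs. List medians with the card mean were 1.25 for the miR-17 cluster, -0.50 for let-7, 1.28 for myeloid, 1.19 for inflammatory, -0.51 for estrogen-associated, 0.35 for miR-30, -1.37 for miR-29, -2.70 for epithelial, -0.88 for chromosome 19 cluster, -0.38 for chromosome 14 cluster and 0.38 for star strands. With RNU44, there were 34 higher and 47 lower miRNAs. List medians with RNU44 were 0.27 for the miR-17 cluster, -1.47 for let-7, 0.31 for myeloid, 0.21 for inflammatory, -1.08 for estrogen-associated, -0.29 for miR-30, -2.35 for miR-29, -3.68 for epithelial, -0.56 for chromosome 19 cluster, -0.56 for chromosome 14 cluster and 0.98 for star strands. Ratios that reversed with RNU44 were -0.64 for miR-302c and -0.38 for miR-24. With RNU48, there were 20 higher and 64 lower miRNAs. List medians with RNU48 were -0.92 for the miR-17 cluster, -2.67 for let-7, -0.89 for myeloid, -0.98 for inflammatory, -2.27 for estrogen-associated, -1.08 for miR-30, -3.54 for miR-29, -4.87 for epithelial, -0.95 for chromosome 19 cluster, -1.35 for chromosome 14 cluster and 0.60 for star strands. Ratios that reversed with RNU48 were -0.27 for miR-19b, -0.92 for miR-106a, -0.90 for miR-17, -0.058 for miR-92a, -0.54 for let-7b, -0.89 for miR-142-3p, -1.02 for miR-155, -1.84 for miR-302c, -0.44 for miR-16, -0.88 for miR-15b, -0.99 for miR-30b and -1.57 for miR-24. With the mean of RNU44 and RNU48, there were 27 higher and 53 lower miRNAs. List medians with the mean of RNU44 and RNU48 were -0.32 for the miR-17 cluster, -2.07 for let-7, -0.29 for myeloid, -0.38 for inflammatory, -1.68 for estrogen-associated, -0.68 for miR-30, -2.94 for miR-29, -4.27 for epithelial, -0.75 for chromosome 19 cluster, -0.96 for chromosome 14 cluster and 0.79 for star strands. Ratios that reversed with the mean of RNU44 and RNU48 were -0.32 for miR-106a, -0.30 for miR-17, -0.29 for miR-142-3p, -0.42 for miR-155, -1.24 for miR-302c, -0.28 for miR-15b, -0.39 for miR-30b and -0.98 for miR-24. With no scaling, there were 35 higher and 45 lower miRNAs. List medians with no scaling were 0.035 for the miR-17 cluster, -1.71 for let-7, 0.068 for myeloid, -0.025 for inflammatory, -1.32 for estrogen-associated, -0.18 for miR-30, -2.58 for miR-29, -3.91 for epithelial, -0.46 for chromosome 14 cluster and 1.43 for star strands. Ratios that reversed with no scaling were -0.062 for miR-155, -0.88 for miR-302c, -0.034 for miR-30b and -0.62 for miR-24. List medians with a Ct limit of 32 were -0.32 for let-7, 0.47 for miR-30, -1.46 for epithelial, 0.035 for chromosome 19 cluster, 1.12 for chromosome 14 cluster and 0.96 for star strands. With a Ct limit of 30, there were 34 higher and 11 lower miRNAs. List medians with a Ct limit of 30 were 2.34 for myeloid, 0.99 for inflammatory, -0.11 for estrogen-associated, 0.47 for miR-30, -1.46 for epithelial, 0.15 for chromosome 19 cluster, 1.69 for chromosome 14 cluster and 0.94 for star strands. List medians with any Ct in both samples were 0.28 for let-7, 0.035 for chromosome 19 cluster, 0.56 for chromosome 14 cluster and 1.40 for star strands. List medians with assays with a Ct under 15 left out were 0.50 for miR-29 and 0.96 for star strands. With Ct near a whole cycle left out, there were 22 higher and 12 lower miRNAs. Median log2 ratios of the members left with Ct near a whole cycle left out were 1.78 for the miR-17 cluster, -0.62 for let-7, 3.13 for inflammatory, 3.55 for estrogen-associated, 0.15 for chromosome 19 cluster, 0.56 for chromosome 14 cluster and 0.96 for star strands. With a 1.5-fold threshold, there were 31 lower miRNAs. With card A alone, there were 36 higher and 11 lower miRNAs. With card B alone, there were 20 higher and 9 lower miRNAs. With random lists matched on size alone, the epithelial percentile was 0.85. With matching on card and Ct, no list of at least 3 members lay outside the central 95% of random lists. Those random lists spread widely, for let-7 from -1.62 to 2.67 in median log2 ratio, so a shift of 1 cycle could be missed. The counts detected in 1 pool alone stayed within 1.5 times under every limit run, as did both counts with a 3-fold threshold, a Ct limit of 32, any Ct, human main arms alone and Ct under 15 left out. U6 recomputed from raw Ct and the authors' fold gave the main values again by construction. A Ct limit leaves a named ratio as it is or removes the miRNA. With Ct near a whole cycle left out, the miR-30 and myeloid lists had no member left, and the values for the miR-17 cluster, inflammatory, estrogen-associated and epithelial lists are those of 1 miRNA each and that for let-7 of 2, so they are not list medians to compare with the main ones. At a Ct limit of 32 the epithelial and at 30 the myeloid, inflammatory and epithelial lists kept 2 members, the miR-29 list kept 1 at either limit, and miR-29 kept 2 with Ct under 15 left out. Card counts are lower because fewer miRNAs enter; the cause of the other shifts was not tested, beyond the reference RNA that each scaling sets. Wells of late Ct limit the detection calls, as 15 of 52 at Ct 30 to 35 with vehicle and 20 of 60 with estradiol had no Ct in the other pool.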

Other observations

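All tests in this part were chosen after the values they measure had been seen.

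Among assays with a Ct of 15 to 30 in 1 pool, a range well inside the detection limit, 11 of 106 with vehicle and 9 of 107 with estradiol were undetermined in the other pool. Chosen after their values were seen, examples are miR-148a, with no Ct with vehicle and 22.1 with estradiol, and miR-708, with 24.1 with vehicle and no Ct with estradiol.

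On card A, U6 was 1.89 cycles later with estradiol, which raises every card A ratio to U6. Less U6 RNA in the estradiol pool as the whole cause is argued against by card B, run from the same pooled RNA, where U6 differed by -0.25 cycles. A lower yield of the whole card A reaction as the whole cause is argued against by the controls, whose card A minus card B differences ranged over 2.26 cycles, from 2.14 for U6 to -0.12 for RNU48. A partial loss of yield stays open, since the raw median log2 ratio of card A miRNAs was -0.92, and so does a fault shared by all 4 card A U6 wells, which was not tested. A fault of single U6 wells is argued against by their agreement, with SD 0.086 cycles with vehicle and 0.070 with estradiol. No explanation by an effect of estradiol on U6 itself was tested beyond card B.

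A Ct under 15 was given by 33 assays in at least 1 pool, among them chromosome 19 cluster members, and 4 of the 20 largest differences are such assays. Very abundant RNA in both samples was examined as the cause of the whole set. The samples lay within 3 cycles in 36.4% of them (95% exact confidence interval 20.4 to 54.9), an undetermined pool counting as apart, against 67.2% of assays with a lowest Ct of 20 to 30 (two-sided Fisher's exact test over assays, p = 0.0022). That contrast rests on undetermined wells, in 17 of the 33 assays against 18 of 116, since with a Ct in both pools 12 of 16 and 78 of 98 lay within 3 cycles. It cannot decide the question, because a well that failed to amplify would count as apart even if the RNA was abundant. For the 12 assays within 3 cycles abundant RNA was not settled, as no other measure of them was used here. Taken at face value, their ratios to U6 ran from 482 for miR-628-5p to 174751 for miR-521, both with estradiol. These ratios rest on the same early Ct, and whether such levels are real was not tested. The other assays were early with estradiol in 8 and with vehicle in 13, and a response to estradiol may account for some of them, but with 1 pool per treatment it cannot be told apart from failed or spurious amplification.

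Ct values gathered near whole cycles. Of 405 miRNA wells with a Ct, 138 (34.1%, 95% exact confidence interval 29.5 to 38.9) lay within 0.05 of a whole cycle, where even fractional parts give 10.0%. A fault of card A alone is argued against by card B, where the lowest lower bound of the 2 runs was 14.8%. The share was 11.5% at Ct under 20, 32.99% at 20 to 30 and 44.7% at 30 to 40, and 4 of 24 control wells were near a whole cycle. No biological explanation was tested, and the Ct software remains a candidate source that these tables do not decide.

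As a hypothesis, miRNAs of neighbouring genes could change together through shared transcripts. Over 44 neighbouring pairs of 38 miRNAs, the median difference in change within pairs was 1.41 cycles, the median of 10000 permutations within card was 1.79, and 13.2% of permutations were as small. Some miRNAs, such as miR-19b and miR-92a, were paired with both miR-17 and miR-106a, so which gene gave their RNA is not known. The pairs thus neither bear out nor exclude a shared change.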
